A study of Mus musculus with 24 samples.

How the data were processed

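RNA-seq was measured in large-intestine epithelial cells from C57BL/6J mice, in 24 libraries of 6 groups with 4 each. Per the labels, cells were released from the opened colon with EDTA and dithiothreitol, CD45+ cells were removed on a Percoll density gradient, and purity was assessed by flow cytometry for CD45, EpCAM and cytokeratin 18. Libraries were made with a stranded mRNA kit and sequenced as single reads on an Illumina sequencer.

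The deposited table gives 2 signal values per gene and library, which the authors made with FastQC, Trimmomatic, kallisto (pseudoalignment of reads to transcripts) and sleuth against mm10, with no versions stated. The signal used here is the deposited scaled reads per base: estimated reads per base summed over the transcripts of a gene, multiplied by a length per gene and divided by a size factor per library. The other deposited signal, TPM (abundance relative to the library total) divided by the same kind of factor, was not used, since it differs from the first by a constant per gene and a constant per library. The values are not whole read counts. Among genes with 1 transcript, 48.1% to 56.8% of values from 0.3 to 25 lay within 0.05 reads of a whole number after a step per library was divided out, against 10% by chance. That step gave the estimated reads per library, from 3731530 to 4885800. No interval from counting was computed, since read counts were not recovered for most genes, and the spread between libraries is given in its place.

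The table holds 13107 Ensembl gene IDs, of which 13006 matched a symbol, coordinates, length and GC content in GENCODE vM21 (mm10) and 101 did not. Genes with a value of at least 10 in at least 4 libraries and a total of at least 15 were tested, 11853 in all. Values were scaled by the trimmed mean of M values (TMM, own code), a pseudocount of 1 was added and log2 was taken. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all libraries, with a robust trended variance prior, and tested 9 contrasts: 3 of DSS against day 0, 2 of housing, 2 of the agonist and 2 interactions. P-values are two-sided and Benjamini-Hochberg adjusted over the tested genes of a contrast, and genes under 0.05 were called. The plan made before the data were examined assumed read counts. It named edgeR for the main test and DESeq2 as an alternative, which were not used, because the deposited values are not counts.

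Genes were named by a rule fixed before the data were examined: per contrast the 10 largest and 10 most negative log2 fold changes among called genes with a mean of at least 5 CPM (level relative to the library total) and, for contrasts of 2 groups, no overlap between the groups, without gene models lacking an approved-style symbol. A pair of groups of 4 without overlap arises by chance in 2.86% of genes. For each gene list described, up to 4 called members with the smallest p were named, or the member with the smallest p where none was called. Lgr5, Muc2, Epcam and Ptprc served as checks of the samples. Of these genes, a part is given in the text, and the others are not reported here.

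Of 39 gene lists fixed at the same time, 35 had at least 3 measured members and were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with the correlation estimated, and with fry. Members called were counted over all tested genes and adjusted over the list alone. Overlaps of called genes were set beside the number for independent lists. The agonist and housing changes were correlated across genes and set beside 200 simulations of unchanged groups that share the vehicle libraries.

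Alternatives fixed before the data were examined were median-of-ratios scaling, limma voom, no filter and a stricter filter, only the compared groups in the fit, replicate number as a block, each library left out in turn, and the shared vehicle libraries split 2 and 2. Added after the data were seen were the deposited scaling, pseudocounts of 0.5 and 5, a correction that removes from each library a spline trend (5 degrees of freedom) of its deviations on GC content and length (11762 genes), the same with replicate block, and each library's GC slope as a term of the fit. The limma procedure was tested on simulated data with 200 changed genes and no GC trend: 20.9% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, with 8 false calls, and 0 genes were called without a change. With the GC trends of the real libraries these shares were 8.96%, 43.3% and 90.9% uncorrected and 12.1%, 59.7% and 93.9% corrected. Simulated libraries with the GC trends of the real ones and no changed gene gave 3452 false calls for DSS at 30 °C with vehicle, 41 with the agonist and 5 for the agonist at day 0, and 0 in each after the correction. The simulated trends were linear in GC content, without a length trend, and the correction removes a trend on that same GC content. The last result was therefore bound to follow and does not test the correction on the real libraries. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.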

Results

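RNA from large-intestine epithelial cells of C57BL/6J mice was sequenced in 24 libraries that fall into 6 groups of 4. Mice were housed at 22 °C or at 30 °C, a temperature near thermoneutrality for mice, and were sampled before (day 0) or on day 3 of 4% dextran sodium sulfate (DSS), a compound given in drinking water that injures the colon epithelium. At 30 °C, mice received either vehicle or CL 316,243, an agonist of the β3-adrenergic receptor, at 1 mg/kg for 2 weeks before DSS. The groups are written T22_D0, T22_D3, T30_D0, T30_D3, T30_CL_D0 and T30_CL_D3, for temperature, agonist and day. The labels number the libraries of a group 1 to 4 and do not say that each came from a separate mouse, so p-values measure only the spread between these libraries. Each library held an estimated 3731530 to 4885800 reads. Fold changes are on a log2(value + 1) scale with their standard error, adjusted p-values come from limma, and group levels are normalised values as mean ± SD (n = 4). The standard error of a gene uses 1 variance over all 6 groups, so it does not follow the spread of the groups compared. It can be too large for quiet groups and too small for variable ones.

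The preparations differed between groups beyond single genes. The cells were cleared of CD45+ cells on a density gradient. Epcam, an epithelial surface protein, had normalised values of 6433 ± 197 in T22_D0, 6862 ± 603 in T22_D3, 6542 ± 311 in T30_D0, 6635 ± 659 in T30_CL_D0, 6209 ± 1375 in T30_D3 and 4802 ± 753 in T30_CL_D3. Ptprc, which encodes CD45, lay between 3.89 and 14.5 as a group mean. Transcripts of the mitochondrial genome took 16.5% ± 2.37 of the signal in T22_D0 and 16.8% ± 2.01 in T30_D0. The share was 12.2% ± 4.34 in T22_D3, 9.28% ± 3.24 in T30_CL_D0, 5.53% ± 3.25 in T30_D3 and 4.54% ± 2.14 in T30_CL_D3. The slope on transcript GC content was taken from log2 values after the mean of each gene over all 24 libraries was subtracted. This slope, relative to the average library, rose from -0.55 per 10 GC points in T22_D0 to 0.77 in T30_CL_D3. The first principal component held 59.9% of the variance, and its gene loadings followed GC content (Spearman 0.624 across genes, which are not independent). Counts below are therefore given also after a smooth trend on GC content and transcript length was removed from each library, a correction chosen after the data were seen.

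**Figure D1:**
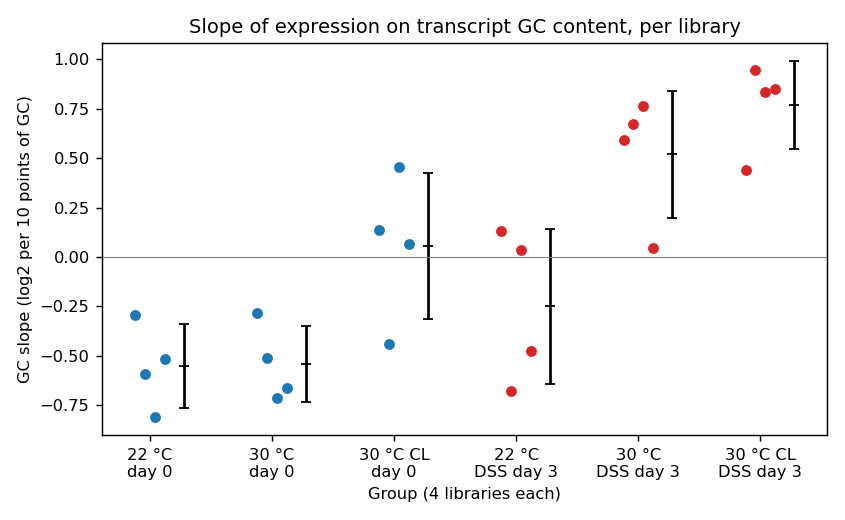
Slope on transcript GC content of log2 expression relative to the mean of all 24 libraries. Points are libraries of the 6 groups, in log2 units per 10 points of GC, with the group mean and SD (bars, n = 4). All 8 DSS day 3 libraries at 30 °C lie above -0.28, the highest of the day 0 vehicle libraries.

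At 22 °C, 3 days of DSS raised genes of mucosal defence and wound repair and lowered genes of crypt stem cells. Slpi, a secreted inhibitor of leukocyte proteases (ENSMUSG00000017002, chromosome 2, 164354070 to 164389095, mm10), went from 5.12 ± 3.26 to 103 ± 26.6, a log2 fold change of 4.23 ± 0.40. Reg3b and Reg3g, C-type lectins that bind bacteria, rose by 3.50 ± 0.87 (adjusted p = 0.0383) and 2.51 ± 0.56. Aldh1a3, a retinaldehyde dehydrogenase, rose by 4.00 ± 0.45, Ido1, which breaks down tryptophan, by 2.45 ± 0.46, and Clca4b by 3.61 ± 0.82. Smoc2, a marker of crypt stem cells (ENSMUSG00000023886, chromosome 17, 14279506 to 14404790), went from 117 ± 20.7 to 30.2 ± 9.13, a log2 fold change of -1.95 ± 0.29. The Wnt target Axin2 (-1.74 ± 0.40), the NADPH oxidase gene Nox1 (-1.96 ± 0.32), the phospholipase gene Pla2g4c (-3.20 ± 0.76), the matrix gene Prelp (-2.95 ± 0.52) and the endothelin gene Edn1 (-1.66 ± 0.30) fell.

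Of the gene lists fixed in advance, wound repair and fetal-like epithelium had 6 of 20 measured members higher and none lower (11 higher and 1 lower adjusted over the list alone), led by Ly6a (2.74 ± 0.25), Ly6c1 (3.88 ± 0.52), Anxa8 and Krt7. Its camera test held with an estimated correlation (adjusted p = 0.00390). Mucosal defence had 6 of 19 members higher and 1 lower, the lectin Reg4 (11 higher and 3 lower adjusted over the list alone; camera adjusted p = 1.47e-04, and 0.175 with an estimated correlation). Crypt stem and progenitor cells had 4 of 17 members lower, Smoc2, Axin2, Ephb3 and Cdca7 (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 1.66e-07, and 0.0800 with an estimated correlation). The stem cell gene Lgr5 had a log2 fold change of -1.87 ± 0.60 and did not pass (adjusted p = 0.119). The interferon list had 4 of 28 members higher, Zbp1, Gbp2, Iigp1 and Igtp (7 higher and 1 lower adjusted over the list alone). Antigen presentation had 3 of 20 higher, Psmb8, Cd74 and Tap1 (12 higher and 0 lower adjusted over the list alone). Goblet cells had 3 of 19 higher, Zg16, Agr2 and Muc2 (7 higher and 0 lower adjusted over the list alone). Muc2 lost its call after GC correction (adjusted p = 0.0923). The unfolded protein response had 4 of 23 higher, Creld2, Asns, Pdia6 and Calr (10 higher and 1 lower adjusted over the list alone), and cholesterol biosynthesis 2 of 25, Fdft1 and Fdps (9 higher and 0 lower adjusted over the list alone). The camera tests of these 5 lists gave adjusted p from 1.66e-07 to 0.00101 with the preset correlation, and from 0.161 to 0.321 with an estimated correlation. In the cell cycle list no member was called, and its mean log2 fold change was -0.35 (camera adjusted p = 1.06e-04, and 0.170 with an estimated correlation). In all, 239 of 11853 genes were called at adjusted p under 0.05, 182 higher and 57 lower, and 208 of them stayed called with the same sign after GC correction. The count was 108, 90 and 106 without T22_D0 replicates 2, 3 and 4 in turn and 122 and 76 without T22_D3 replicates 1 and 3 in turn. Of the 36 called genes named for this comparison, 15 kept their call whichever library was left out and 31 with GC slope as a term. Muc2 (13 of 20), Igtp and Tap1 (11 of 20 each), Pdia6 and Reg3b (10 of 20 each), Agr2 and Calr (9 of 20 each), Cdca7 (8 of 20), Ephb3 and Fdps (7 of 20 each), Asns, Pla2g4c and Reg3g (6 of 20 each) and Clca4b, Creld2 and Fdft1 (5 of 20 each) lost their call in at least 25% of the alternative settings.

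At 30 °C with vehicle, the genes with the largest rise on DSS day 3 were those of MHC class II, which presents peptides to CD4 T cells, together with interferon-stimulated genes. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) went from 13.4 ± 4.71 to 1128 ± 1037, a log2 fold change of 5.85 ± 0.51, and the invariant chain gene Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652) from 82.4 ± 13.4 to 4583 ± 3630.3 (5.47 ± 0.44). H2-Ab1 (5.61 ± 0.52), H2-Eb1 (4.86 ± 0.46), H2-DMa (4.15 ± 0.49) and H2-DMb1 (5.14 ± 0.51) rose with them. Isg15, an interferon-induced ubiquitin-like protein (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), went from 8.45 ± 3.02 to 242 ± 174 (4.41 ± 0.51), and Apol9b rose by 4.97 ± 0.49. The kinase gene Camk4 (-3.72 ± 0.54), Pla2g4c (-3.59 ± 0.76), Pakap (-3.98 ± 0.63), Paxbp1 (-3.64 ± 0.59), Trappc8 (-4.05 ± 0.81), Gvin1 (-4.96 ± 0.94), Zfp97 (-4.53 ± 0.70) and the splicing factor gene Prpf39 (-4.46 ± 0.65) fell. After GC correction these 8 genes stood at -3.74, -2.58, -3.29, -2.84, -2.46, -2.67, -2.39 and -2.38, all still called. With GC slope as a term they stood at -1.57, -3.23, -3.68, -1.59, -1.40, -2.79, -1.92 and -2.44, and 7 of the 8, all but Pakap, were not called. The corrected values were 5.55 for H2-Aa, 4.82 for Cd74 and 3.93 for Isg15. The processed pseudogenes Rab11b-ps2 (4.61 ± 0.76), Rps25-ps1 (4.06 ± 1.15) and Rpl28-ps1 (-6.73 ± 1.37) share sequence with their parent genes, so their values are uncertain.

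Antigen presentation had 20 of 20 measured members higher (20 higher and 0 lower adjusted over the list alone; 18 after GC correction), among them the immunoproteasome gene Psmb8 (3.60 ± 0.27), with a camera adjusted p of 5.72e-11, and 0.361 with an estimated correlation. The interferon list had 18 of 28 higher and 1 lower (18 higher and 1 lower adjusted over the list alone), with Zbp1 (2.64 ± 0.25), Oasl2 (3.19 ± 0.32) and Oas1a (2.31 ± 0.25) besides Isg15 (camera adjusted p = 1.44e-04, and 0.480 with an estimated correlation). Beside these, markers of T cells and intraepithelial lymphocytes had 5 of 8 members higher (5 higher and 0 lower adjusted over the list alone), among them Gzma, Cd7, Cd8a and Ccl5, and Gzma went from 6.35 ± 4.30 to 90.2 ± 48.5. Macrophage markers had 4 of 8 higher, Cd14, Lyz2, C1qa and Fcer1g (4 higher and 0 lower adjusted over the list alone), of which only Lyz2 stayed called after GC correction. With GC slope as a term none of these 4 was called (Lyz2 1.23). Of the T cell markers, Ccl5 (1.06) and Cd7 (2.00) lost their call in that fit, and Gzma (3.31) and Cd8a (2.75) kept it. B and plasma cell markers had 0 of 3 higher, with Ighm at 1.07 ± 0.57 (0 higher and 0 lower adjusted over the list alone). Camera did not call these 3 lists (adjusted p = 0.0841, 0.315 and 0.724).

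Energy metabolism split by genome in the same comparison. Nuclear genes of oxidative phosphorylation had 45 of 51 members higher and 1 lower (45 higher and 1 lower adjusted over the list alone), led by Atp5o (1.55 ± 0.20), Cox6b1, Sdhb and Cox4i1. After GC correction Atp5o stood at 1.08 and Cox6b1 at 0.45, in place of 1.54. All 12 measured genes of the mitochondrial genome fell (0 higher and 12 lower adjusted over the list alone), mt-Atp6 (-3.65 ± 0.30) and mt-Nd2 (-2.49 ± 0.29) among them. After GC correction 8 mitochondrial genes remained called, mt-Atp6 at -1.81 and mt-Nd2 at -0.56. Ribosomal proteins had 29 of 36 higher and 3 lower (29 higher and 3 lower adjusted over the list alone; 18 and 3 after GC correction), with Rps2, Rplp0, Rplp2 and Rpl27 leading at 1.39 to 1.62, and 0.67 to 0.83 after the correction. Glycolysis and hypoxia had 17 of 26 higher and 2 lower (17 higher and 2 lower adjusted over the list alone), with Gapdh, Eno1, Gpi1 and Pkm rising by 1.45 to 1.61, and by 0.73 to 0.97 after the correction. Camera called these 4 lists with the preset correlation (adjusted p from 1.16e-10 to 7.47e-04) and none with an estimated correlation (adjusted p from 0.480 to 0.706). Cox6b1 (0.80), Sdhb (0.52), Cox4i1 (0.70), Rps2 (0.67), Rplp0 (0.37), Rplp2 (0.51) and Rpl27 (0.44) were not called with GC slope as a term. Atp5o (0.76), Gapdh, Eno1, Gpi1 and Pkm (0.65 to 0.95), mt-Atp6 (-2.14) and mt-Nd2 (-1.16) kept their call in that fit. The hormone genes Pyy (2.08 ± 0.25), Sst (1.85 ± 0.34), Insl5 and Sct were among 10 of 16 enteroendocrine members that rose (11 higher and 2 lower adjusted over the list alone; 2 fell; camera adjusted p = 0.0768). Corrected for GC content, Pyy stood at 1.15 and Sst at 1.14, and Sct lost its call (0.56, adjusted p = 0.232). Sst (1.19), Insl5 (0.70) and Sct (1.19) were not called with GC slope as a term, and Pyy (1.29) was. Crypt stem and progenitor cells had 7 of 17 lower and 1 higher (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.303), with Aqp4 (-1.90 ± 0.39), Znrf3, Sox9 and Slc12a2, the last 2 at -0.57 and -0.02 after GC correction, which ended the call of Slc12a2. With GC slope as a term Aqp4 (-0.05), Znrf3 (-0.75), Sox9 (-1.28) and Slc12a2 (-0.46) were not called. In all, 7647 genes were called, 3820 higher and 3827 lower, of which 4481 (58.6%) stayed called with the same sign after GC correction. The split was 3263 higher and 2543 lower after that correction and 3306 higher and 4319 lower with the deposited scaling. The deposited scaling shifts the median of all genes by -0.14 in this comparison. With each library's GC slope as a term of the fit, 565 were called. Of the 56 called genes named for this comparison, 55 kept their call whichever library was left out and 24 with GC slope as a term. Fcer1g (9 of 19) lost its call in at least 25% of the alternative settings.

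At 30 °C with CL 316,243, ribosomal, nuclear respiratory and immediate early genes were higher on DSS day 3 than at day 0. Another split of these 8 libraries called 5682 genes against 5454. With 2 of 35 splits calling as many, the count does not argue against chance. Exchanged labels between T30_CL_D0 and T22_D3 stay open, as described below, which limits each contrast with T30_CL_D0. Mki67, a marker of dividing cells, fell by 2.76 ± 0.32, Tjp1 (the junction protein ZO-1) fell by 2.26 ± 0.33, Clca4b fell by 3.21 ± 0.82 and Adgrf1 fell by 2.80 ± 0.69, and after GC correction they stood at -1.84, -2.01, -2.22 and -1.99. Ttr (transthyretin) rose by 2.14 ± 0.33, the bile acid binding protein gene Fabp6 by 2.69 ± 0.72, Gzma by 2.48 ± 0.53, Ccdc36 by 5.08 ± 0.61, H2-Aa by 2.02 ± 0.51 and H2-Ab1 by 2.02 ± 0.52. With GC slope as a term H2-Aa (1.39), H2-Ab1 (1.12), Gzma (2.26), Fabp6 (3.08), Clca4b (-1.21) and Adgrf1 (-2.02) were not called. Mki67, Tjp1, Ttr and Ccdc36 kept their call in that fit. Immediate early genes had 15 of 21 members higher and 1 lower (16 higher and 1 lower adjusted over the list alone), led by Klf2 (1.88 ± 0.24), Zfp36, Junb and Ier2. Antigen presentation had 10 of 20 higher (11 higher and 0 lower adjusted over the list alone). The interferon list had 2 higher and 7 lower of 28 (2 higher and 7 lower adjusted over the list alone), with Gbp2 (-1.57 ± 0.36), Gbp7 and Parp14 falling, of which Parp14 lost its call after GC correction (adjusted p = 0.155). With GC slope as a term Gbp2 (-1.40), Gbp7 (-1.32) and Parp14 (-0.63) were not called. Cell junctions had 12 of 24 lower and 3 higher (5 higher and 12 lower adjusted over the list alone), with Mylk and Dsp lower and the claudin gene Cldn4 higher (1.58 ± 0.31). NRF2 and xenobiotic genes had 12 of 27 higher and 4 lower (12 higher and 4 lower adjusted over the list alone), with Gsta3 (1.68 ± 0.23), Nqo1, Ces1g and Mgst1. Ribosomal proteins had 31 of 36 higher (31 higher and 0 lower adjusted over the list alone). Nuclear oxidative phosphorylation genes had 39 of 51 higher and 1 lower (40 higher and 1 lower adjusted over the list alone), and mitochondrial genes 11 of 12 lower (0 higher and 11 lower adjusted over the list alone). Of these lists, camera with the preset correlation called all but the interferon and junction lists (adjusted p = 0.146 and 0.220), and with an estimated correlation none (adjusted p from 0.310 to 0.812). All 3 measured B and plasma cell markers, Igkc (2.08 ± 0.50), Igha (2.61 ± 0.69) and Ighm, rose (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0815). None of them was called with GC slope as a term (Igkc 1.90, Igha 2.69 and Ighm 1.08). T cell markers had 4 of 8 higher and 1 lower, Ptprc, which was not called after GC correction (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0991). In all, 5454 genes were called, 2413 higher and 3041 lower (2860 kept with the same sign after GC correction). The balance turned after that correction, to 2116 higher and 1740 lower. The count was 3549 with only these 8 libraries in the fit, 3592 without T30_CL_D3 replicate 4 and 258 with GC slope as a term. Of the 28 called genes named for this comparison, 26 kept their call whichever library was left out and 11 with GC slope as a term. Ptprc (8 of 19) and Ighm (7 of 19) lost their call in at least 25% of the alternative settings.

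**Figure D2:**
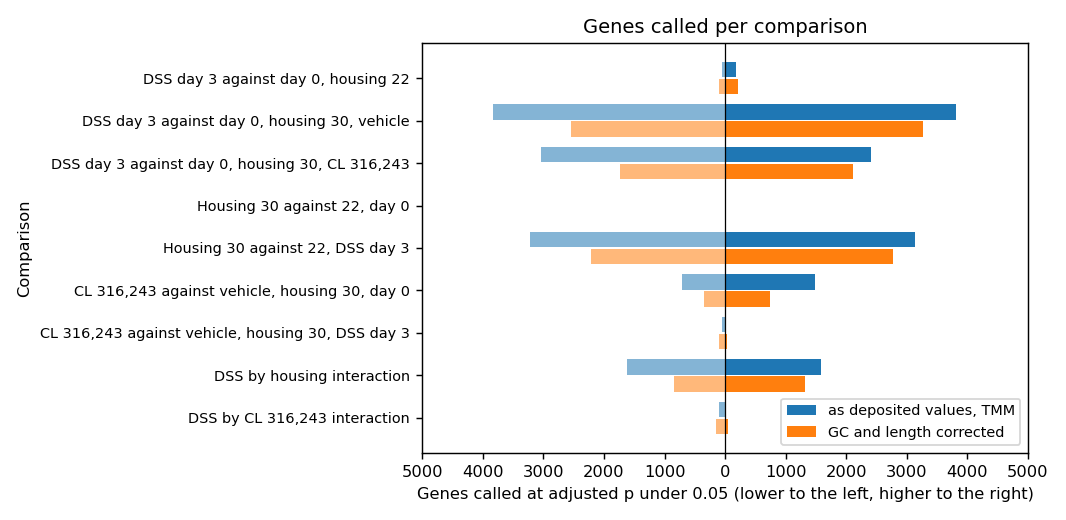
Number of genes called at adjusted p under 0.05 per comparison, higher to the right and lower to the left, from the TMM-scaled values (blue) and after GC and length correction (orange). DSS at 30 °C with vehicle gave 7647 and 5806 genes, and DSS at 22 °C 239 and 326.

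The 3 DSS responses overlapped unevenly, and share no library. Of the 182 genes raised at 22 °C, 138 were also raised at 30 °C with vehicle, against 58.7 for independent lists of these sizes, and of the 57 lowered genes 28 were also lowered, against 18.4. With the agonist at 30 °C the same counts were 38, against 37.1, and 8, against 14.6, and 25 raised and 13 lowered genes were called in the opposite direction. Between 22 °C and 30 °C with vehicle 2 and 6 were opposite. Vehicle and agonist at 30 °C shared 2115 raised genes, against 778, and 2564 lowered genes, against 982. After GC correction they shared 1664 raised and 1286 lowered genes, against 587 and 376, and with GC slope as a term 75 in all. Across genes, which are not independent, log2 fold changes at 22 °C and 30 °C with vehicle had a Pearson r of 0.527 (0.390 after GC correction). It was 0.308 (0.102) at 22 °C and 30 °C with agonist, and 0.826 (0.720) at 30 °C with vehicle and with agonist. The closeness of same-numbered libraries can raise the overlap of 22 °C with 30 °C vehicle, through T22_D0 and T30_D0, and lower that of 22 °C with 30 °C agonist, through T22_D3 and T30_CL_D0, and the independent lists do not allow for it. With 2 libraries per group and different replicate numbers, r averaged 0.405 (0.156 to 0.572) over 6 choices for 22 °C and 30 °C vehicle and 0.249 (-0.0227 to 0.499) for 22 °C and 30 °C agonist. With the same numbers it averaged 0.421 (0.130 to 0.652) and 0.188 (-0.00447 to 0.335), a check chosen after the data were seen, in which a closeness of whole groups remains. All 3 responses shared 44 genes, 37 raised and 7 lowered. This became 26 with median-of-ratios scaling, 24 under a stricter filter and 1 with GC slope as a term. The 166 genes shared by 22 °C and 30 °C vehicle became 104 under a stricter filter and 62 with GC slope as a term. The number was 78, 62 and 77 without T22_D0 replicates 2, 3 and 4 in turn and 80 and 53 without T22_D3 replicates 1 and 3 in turn. With GC slope as a term, 22 °C and 30 °C with agonist shared 1 gene. The 46 genes shared by 22 °C and 30 °C with agonist numbered 14, 11 and 18 without T22_D0 replicates 2, 3 and 4 in turn, 20 and 9 without T22_D3 replicates 1 and 3 in turn. It was 30 and 22 without T30_CL_D0 replicates 1 and 2 in turn, 101, 24, 27 and 27 without T30_CL_D3 replicates 1, 2, 3 and 4 in turn. It was 83 without T30_D3 replicate 4. The 44 genes shared by all 3 numbered 14, 11 and 18 without T22_D0 replicates 2, 3 and 4 in turn, 20 and 9 without T22_D3 replicates 1 and 3 in turn. It was 29 and 21 without T30_CL_D0 replicates 1 and 2 in turn, 96, 24, 26 and 25 without T30_CL_D3 replicates 1, 2, 3 and 4 in turn. It was 80 without T30_D3 replicate 4.

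Before DSS, no gene separated housing at 30 °C from 22 °C in the main test. In limma 0 of 11853 genes were called and 96 had an unadjusted p under 0.05, fewer than the 593 that chance would give, and limma voom called 1. Epcam (0.02 ± 0.14), Muc2 (-0.04 ± 0.27), Lgr5 (0.20 ± 0.60) and Ptprc (0.01 ± 0.66) differed by less than 1 standard error each. These standard errors use the variance over all 6 groups and can exceed the spread of the day 0 libraries. The mucosal defence gene Itln1 had a log2 fold change of 1.03 ± 0.48, the cell cycle gene Cenpf -1.13 ± 0.66 and the immediate early gene Ier3 0.32 ± 0.26, with adjusted p = 1.00 each. Camera with the preset correlation called mucosal defence, cell cycle and immediate early genes (adjusted p = 0.0141, 0.0176 and 0.0141). None held with an estimated correlation (adjusted p = 0.717, 0.727 and 0.898), and none of their members was called (0 higher and 0 lower adjusted over the list alone, for each list). Among the libraries of the other group, each of the 8 libraries was closest to that of the same replicate number. Within its own group, T30_D0 replicate 3 was closer still to replicate 4 (2.29 against 2.36). The closeness was the median squared difference relative to read sampling alone, 2.00 to 2.36 for same-numbered pairs against at least 2.61 for other pairs across the groups and 2.29 within any group, a check made after the data were seen. The mean standard error was 0.317 on the log2 scale. The test takes the libraries as independent, and pairs of close libraries can hide changes from it. The 0 called genes therefore do not show that housing changed none.

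On DSS day 3, housing at 30 °C differed from 22 °C in class II, interferon-stimulated and absorptive cell genes, among others. Class II genes were higher at 30 °C, H2-Aa by 4.48 ± 0.51, H2-Ab1 by 4.39 ± 0.52, H2-Eb1 by 3.98 ± 0.46 and Cd74 by 3.83 ± 0.44. So were the nonclassical class I genes H2-Q6 (3.56 ± 0.35) and H2-Q7 (3.57 ± 0.35), near-identical paralogs whose reads can be split between them. Isg15 was higher by 3.35 ± 0.51, the interferon regulator Irf7 by 2.43 ± 0.27 and Apol9b by 3.76 ± 0.49. The water channel gene Aqp8 (2.33 ± 0.30), the antibacterial surface protein gene Lypd8 (1.35 ± 0.19), Cdhr2 and Slc51a led 13 of 26 higher members of the absorptive colonocyte list (3 lower; 13 higher and 3 lower adjusted over the list alone). Acot1 (1.80 ± 0.21), Etfb and Slc25a20 were among the 16 of 32 members of the fatty acid oxidation list that were higher (6 lower; 17 higher and 6 lower adjusted over the list alone). The stem cell gene Lgr5 was higher by 1.48 ± 0.60 and Muc2, the main mucin, was lower (-1.13 ± 0.27), of which Lgr5 was not called in 7 of 20 alternative settings. The cytokine gene Il7 (-3.58 ± 0.50), the insulin signalling gene Irs1 (-3.22 ± 0.61), Naa15 (-3.19 ± 0.56), Zfp948 (-3.18 ± 0.53) and mt-Atp6 (-3.10 ± 0.30) were lower, and stood at -2.34, -2.35, -1.95, -1.91 and -1.65 after GC correction.

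Antigen presentation had 19 of 20 members higher at 30 °C (20 higher and 0 lower adjusted over the list alone), and interferon response 12 of 28 higher and 2 lower (11 higher and 2 lower adjusted over the list alone). Nuclear oxidative phosphorylation genes had 44 of 51 higher (44 higher and 0 lower adjusted over the list alone) and mitochondrial genes 11 of 12 lower (0 higher and 11 lower adjusted over the list alone). T cell markers had 4 of 8 higher, Gzma (3.33 ± 0.53), Cd8a, Cd7 and Ccl5 (4 higher and 0 lower adjusted over the list alone). Camera called these lists and the colonocyte and fatty acid lists with the preset correlation (adjusted p from 2.38e-11 to 0.0233) and none with an estimated correlation (adjusted p from 0.233 to 0.569). In all, 6364 genes were called, 3140 higher and 3224 lower, and 3827 stayed called with the same sign after GC correction. The split was 2720 higher and 3549 lower with the deposited scaling and 2774 higher and 2213 lower after GC correction. With GC slope as a term 1215 were called. Of the 30 called genes named for this comparison, 29 kept their call whichever library was left out and 26 with GC slope as a term. Lgr5 (7 of 20) lost its call in at least 25% of the alternative settings.

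**Figure D3:**
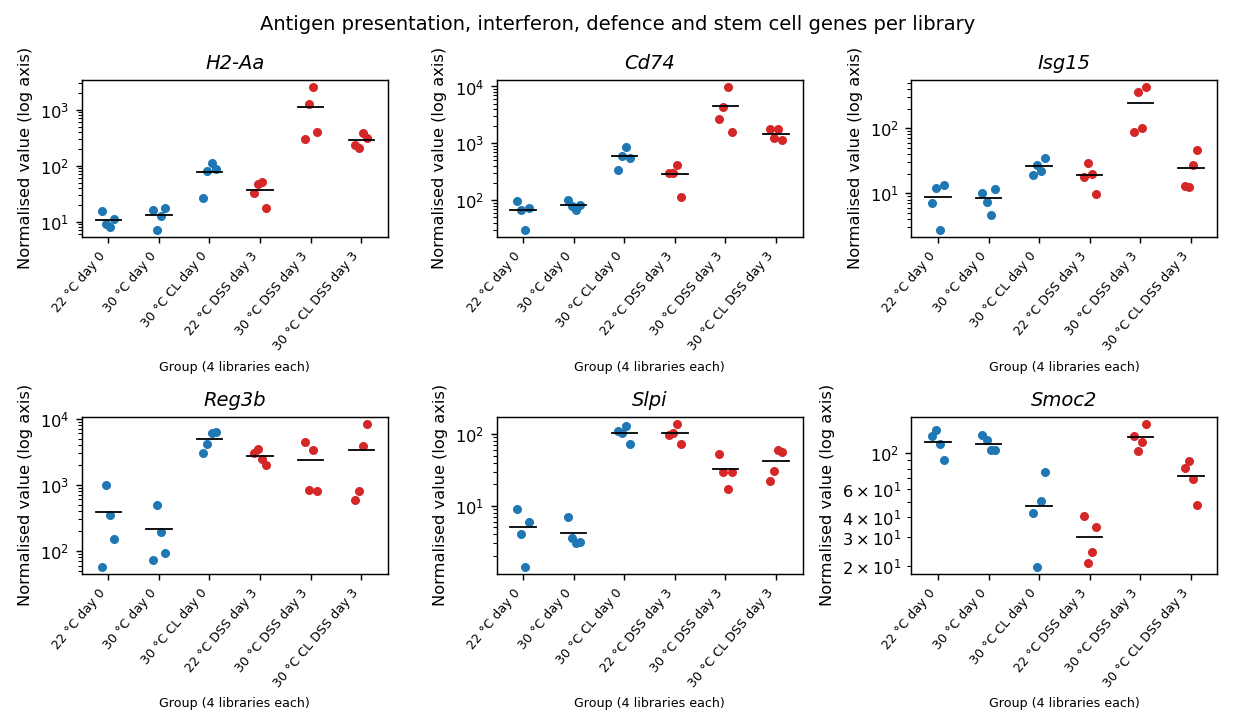
Normalised values (log axis) of 6 genes per library (points) with group means (lines, n = 4), day 0 in blue and DSS day 3 in red. Cd74 averaged 4583 in T30_D3 against 284 in T22_D3, and Smoc2 30.2 in T22_D3 against 124 in T30_D3.

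The test of the difference between both vehicle DSS responses asked which genes DSS changed differently at 30 °C and 22 °C. The class II genes rose more at 30 °C, H2-Ab1 by 4.26 ± 0.73, H2-Aa by 4.24 ± 0.72 and Cd74 by 3.44 ± 0.62 on the log2 scale, as did Apol9b (5.10 ± 0.69), Oas3 (3.43 ± 0.53) and Irf7 (2.35 ± 0.38). Antigen presentation had 15 of 20 members with a higher response at 30 °C (18 higher and 0 lower adjusted over the list alone). The interferon list had 8 of 28 (8 higher and 0 lower adjusted over the list alone). Nuclear oxidative phosphorylation genes had 33 of 51 (39 higher and 0 lower adjusted over the list alone). NRF2 and xenobiotic genes had 9 of 27 (11 higher and 1 lower adjusted over the list alone), with Ces1g (1.92 ± 0.32) and Nqo1 (1.31 ± 0.25). Camera called these 4 lists with the preset correlation (adjusted p from 3.22e-11 to 0.0118) and none with an estimated one (adjusted p from 0.212 to 0.502). T cell markers had 4 of 8 higher, among them Cd8a (2.63 ± 0.57) and Gzma (2.87 ± 0.75), with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0260, and 0.502 with an estimated correlation). Goblet cells had 6 of 19 lower (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.342), with the secreted protein gene Clca1 (-2.50 ± 0.50) and Sytl2 (-2.43 ± 0.55), and Muc2 was lower (-1.09 ± 0.38). Il7 (-3.48 ± 0.70), Naa15 (-3.53 ± 0.80) and the cholesterol exporter gene Abca1 (-3.39 ± 0.73) had lower responses at 30 °C. After GC correction these 3 and Sytl2 stood at -2.24, -2.28, -2.55 and -1.67. The count was 3213 genes, 1590 higher and 1623 lower (1141 higher and 1789 lower with the deposited scaling, 1293 higher and 1689 lower with median-of-ratios scaling, 1315 higher and 851 lower after GC correction), 1521 of them kept with the same sign after GC correction. With GC slope as a term 148 higher and 95 lower were called. The count was 1806 without T22_D0 replicate 1, 1775 and 1830 without T22_D3 replicates 2 and 4 in turn. It was 1847 and 1964 without T30_D0 replicates 3 and 4 in turn and 1484 and 1764 without T30_D3 replicates 2 and 3 in turn. Of the 18 called genes named for this comparison, 16 kept their call whichever library was left out and 11 with GC slope as a term. Muc2 (11 of 28) lost its call in at least 25% of the alternative settings.

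Before DSS, CL 316,243 at 30 °C raised defence, repair and antigen presentation genes against vehicle. Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466) went from 216 ± 198 to 4906 ± 1589 (4.86 ± 0.87, adjusted p = 0.00194), and Slpi from 4.14 ± 1.84 to 104 ± 23.2 (4.38 ± 0.40). Reg3g rose by 3.50 ± 0.56, Clca4b by 3.70 ± 0.82, Slc4a11 by 3.42 ± 0.83, Aldh1a3 by 3.17 ± 0.45 and the lipopolysaccharide-binding protein gene Lbp by 2.93 ± 0.73. Pla2g4c (-4.23 ± 0.76), the antimicrobial ribonuclease gene Ang4 (-2.78 ± 0.53), the lipase gene Pnliprp2 (-2.34 ± 0.43), Abca1 (-2.04 ± 0.52) and Mier3 (-2.08 ± 0.35) fell, as did Prrg1 (-2.24 ± 0.71) and Prpf39 (-2.06 ± 0.65), which lost their call after GC correction. Mucosal defence had 10 of 19 members higher and 3 lower, including Itln1 (-2.52 ± 0.48) (11 higher and 3 lower adjusted over the list alone). Antigen presentation had 14 of 20 higher (17 higher and 0 lower adjusted over the list alone), with Cd74 (2.75 ± 0.44) and H2-DMb1 (2.81 ± 0.51). Interferon response had 8 of 28 higher, with Zbp1, Gbp2, Irf1 and Igtp (9 higher and 1 lower adjusted over the list alone). Wound repair had 10 of 20 higher and 1 lower, with Ly6a (3.13 ± 0.25), Ly6c1 (4.51 ± 0.52), Krt7 and Krt19 (12 higher and 1 lower adjusted over the list alone). Crypt stem cells had 5 of 17 lower, with Axin2 (-1.91 ± 0.40) and Smoc2 (-1.40 ± 0.29) (0 higher and 7 lower adjusted over the list alone). The enteroendocrine peptide genes Tac1 (2.69 ± 0.39), Pyy, Sst and Insl5 rose among 5 of 16 (5 higher and 0 lower adjusted over the list alone), with Insl5 not called after GC correction. The unfolded protein response had 10 of 23 higher, with Creld2, Sdf2l1, Pdia6 and Xbp1 (11 higher and 0 lower adjusted over the list alone). Camera called these 7 lists with the preset correlation (adjusted p from 2.30e-08 to 0.00999) and none with an estimated correlation (adjusted p from 0.0698 to 0.639). Of the adrenergic and thermogenic list, 1 of 14 measured members rose, the protein kinase A gene Prkaca (0.56 ± 0.16), and 2 fell, the coactivator gene Ppargc1a (-0.98 ± 0.28) and Prkar2b (-1.82 ± 0.53) (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.824). Prkaca and Prkar2b lost their call after GC correction (adjusted p = 0.105 and 0.139). In all, 2201 genes were called, 1486 higher and 715 lower (876 higher and 965 lower with the deposited scaling, which shifts the median of all genes by -0.11). Of these, 816 stayed called with the same sign after GC correction. A separate fit with GC slope as a term called 183 genes. The count was 3400, 400 and 1046 without T30_CL_D0 replicates 2, 3 and 4 in turn and 1152, 732 and 840 without T30_D0 replicates 2, 3 and 4 in turn. Of the 39 called genes named for this comparison, 33 kept their call whichever library was left out and 26 with GC slope as a term. Prrg1 (10 of 19), Prkar2b (9 of 19), Prkaca and Prpf39 (8 of 20 each), Insl5 (7 of 20) and Ppargc1a (6 of 20) lost their call in at least 25% of the alternative settings.

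The agonist changes at day 0 and the DSS changes at 22 °C, which share no library, lay close together. Of the 239 genes called with DSS at 22 °C, 215 were called with the same sign for the agonist, 170 higher against 22.8 for independent lists and 45 lower against 3.44. The log2 fold changes had a Pearson r of 0.716 across genes, which are not independent. Neither the independent lists nor r allow for the closeness of T22_D0 to T30_D0 and of T22_D3 to T30_CL_D0 at the same replicate numbers, which can raise both without any change. With 2 libraries per group, r averaged 0.487 (0.261 to 0.629 over 6 choices) where both changes came from different replicate numbers and 0.575 (0.383 to 0.732) where they came from the same, a check chosen after the data were seen. A closeness of whole groups stays in both values. A direct contrast of T30_CL_D0 with T22_D3, added after the data were seen, called 0 genes in limma, with 698 genes at an unadjusted p under 0.05. Exchanged labels between both groups therefore stay open.

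**Figure D4:**
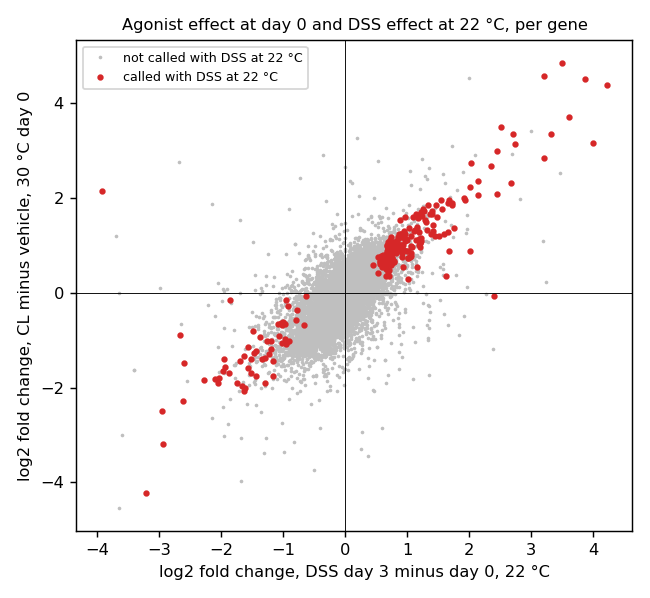
Log2 fold change per gene for DSS at 22 °C (x axis) and for CL 316,243 at day 0, 30 °C (y axis); red points are the 239 genes called with DSS at 22 °C. Of these, 237 have the same sign in both comparisons.

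On DSS day 3 the agonist lowered interferon-stimulated genes against vehicle at 30 °C. Isg15 was 24.8 ± 16.0 with the agonist and 242 ± 174 with vehicle (-3.10 ± 0.51), and Apol9b (-3.40 ± 0.49), Apol9a (-2.93 ± 0.40), Oas3 (-2.89 ± 0.38), Oasl2 (-2.52 ± 0.32), Xaf1 (-2.54 ± 0.55) and Gbp2 (-1.82 ± 0.36) fell with it. Ptpro (-2.58 ± 0.40), Rgcc (-2.62 ± 0.53) and Cpn1 (-1.95 ± 0.35) were also lower. The gasdermin genes Gsdmcl2, Gsdmc2, Gsdmc3 and Gsdmc4 rose by 1.02 to 1.21 as a family of near-identical paralogs whose reads can be shared, and the fatty acid receptor gene Ffar4 (1.00 ± 0.21), Trim46 (1.43 ± 0.31) and Orai2 (1.08 ± 0.18) rose. The interferon list had 7 of 28 members lower (0 higher and 22 lower adjusted over the list alone), and its camera test held with an estimated correlation (adjusted p = 0.0211). Crypt stem cells had 3 of 17 lower, Lgr5 (-2.65 ± 0.60), Ascl2 (-2.54 ± 0.54) and Axin2 (-1.76 ± 0.40) (0 higher and 10 lower adjusted over the list alone; camera adjusted p = 2.17e-07, and 0.0810 with an estimated correlation). Antigen presentation had 1 lower, B2m (0 higher and 4 lower adjusted over the list alone), and absorptive colonocytes 1 lower, Slc9a3 (0 higher and 5 lower adjusted over the list alone). Mucosal defence had 2 higher, both gasdermins (2 higher and 0 lower adjusted over the list alone), and immediate early genes none, with Nr4a1 at 0.90 ± 0.22 (7 higher and 0 lower adjusted over the list alone). Camera gave adjusted p of 3.06e-08, 5.42e-05, 0.195 and 1.62e-07 for these 4 lists, and 0.114, 0.0810, 0.682 and 0.114 with an estimated correlation. In all, 60 genes were called, 14 higher and 46 lower, of which 56 stayed called among 131 after GC correction. A fit of only these 8 libraries called 5. Of 35 splits of these libraries, 7 called as many as the real one, so the count does not argue against chance. The count was 384, 19 and 22 without T30_CL_D3 replicates 1, 2 and 3 in turn and 109, 35 and 17 without T30_D3 replicates 1, 2 and 4 in turn. Of the 22 called genes named for this comparison, 7 kept their call whichever library was left out and 21 with GC slope as a term. Lgr5 (12 of 20), Axin2 (10 of 20), Slc9a3 (9 of 20), Xaf1 (7 of 20), Ascl2 (6 of 19), Trim46 (6 of 20) and Ffar4, Gbp2, Gsdmc2, Gsdmc3 and Gsdmc4 (5 of 20 each) lost their call in at least 25% of the alternative settings.

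The test of the difference between the DSS responses with agonist and with vehicle at 30 °C gave lower responses of interferon, antigen presentation and repair genes with the agonist. Cd74 differed by -4.08 ± 0.62, Isg15 by -4.64 ± 0.72, Oasl2 by -3.95 ± 0.45, Slpi by -3.99 ± 0.56, Apol9b by -5.08 ± 0.69 and Clca4b by -4.78 ± 1.16 on the log2 scale. These genes started higher with the agonist at day 0 than with vehicle. Ang4 (3.75 ± 0.75), the pentraxin gene Mptx1 (3.12 ± 0.57), the prostaglandin receptor gene Ptger3 (1.72 ± 0.41), Nr4a1 (1.70 ± 0.32) and Gsta3 (1.38 ± 0.32) had higher responses. Ptger3 and Gsta3 lost their call after GC correction (adjusted p = 0.0597 and 0.0662). The interferon list had 11 of 28 lower (0 higher and 24 lower adjusted over the list alone), and antigen presentation 11 of 20 (0 higher and 18 lower adjusted over the list alone). Wound repair had 4 of 20 lower, with Ly6a (-3.31 ± 0.36), Anxa8 and Ly6c1 (1 higher and 8 lower adjusted over the list alone). All 3 lists held with an estimated correlation (camera adjusted p = 0.0134, 0.0134 and 0.0472). Glycolysis and hypoxia had 1 lower, Eno1 (0 higher and 12 lower adjusted over the list alone; camera adjusted p = 8.34e-06, and 0.201 with an estimated correlation). In all, 120 genes were called, 18 higher and 102 lower, of which 108 stayed called among 203 after GC correction. A fit of only these 16 libraries called 53. Of 100 splits of these libraries, 6 called as many as the real one, so the count does not argue against chance. These splits mixed day 0 with DSS day 3 libraries, so the DSS change can enter their counts and they do not decide on chance. The deposited scaling shifts the median of all genes by 0.11. The count was 57 and 75 without T30_CL_D0 replicates 3 and 4 in turn, 71 and 199 without T30_CL_D3 replicates 2 and 4 in turn. It was 75 and 65 without T30_D0 replicates 3 and 4 in turn and 67, 59 and 188 without T30_D3 replicates 2, 3 and 4 in turn. Of the 16 called genes named for this comparison, 11 kept their call whichever library was left out and 16 with GC slope as a term. Clca4b (18 of 28), Gsta3 and Ptger3 (13 of 28 each), Eno1 (12 of 28) and Ly6g (7 of 28) lost their call in at least 25% of the alternative settings.

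Whether the agonist acted like housing at 22 °C was asked by correlating, across genes, the change from T30 to T30_CL with the change from T30 to T22. At day 0 Pearson r was 0.184, and unchanged groups that share the T30_D0 libraries gave 0.502 ± 0.0131 in 200 simulations. The covariance was 0.0330 against 0.0639 simulated. The simulation draws each gene independently, while the first principal component held 59.9% of the variance, so its SD leaves out variation shared across genes. It also takes the T22_D0 and T30_D0 libraries as independent, while same-numbered libraries of these groups lay close together. Such closeness lowers r and covariance without any change, so the day 0 values do not show whether the agonist and housing changes are related. On DSS day 3 r was -0.0697 against 0.502 simulated, and the covariance -0.0321 against 0.0638. After GC correction r turned to 0.163, still below the simulated value, and the covariance to 0.0574 against 0.0637. At day 0 the corrected covariance was 0.0349 against 0.0634. With the shared libraries split 2 and 2, the mean r of the 6 splits was -0.0258 at day 0 (-0.275 to 0.173) and -0.184 on DSS day 3 (-0.500 to 0.166), with splits on both sides of 0. The day 0 value was -0.0013, 0.339 and 0.393 without T22_D0 replicate 1, T22_D0 replicate 3 and T30_D0 replicate 1, and the DSS day 3 value turned positive without T30_D3 replicate 1 (0.131), T30_D3 replicate 4 (0.0945) or T30_CL_D3 replicate 4 (0.115).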

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

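The splits of the libraries were planned; the tests of GC content, of carried-over cells and of the nearness of T30_CL_D0 and T22_D3 were chosen after the results were seen.

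Single libraries stood apart from the other 3 of their group in 5 of 66 groups of values tested, where chance gives about 1 in 20. T30_CL_D0 replicate 4 had 171 genes at 0 against 182 to 183 in the others. In T30_D0 replicate 1 the 10 most abundant genes took 20.6% of the signal against 22.9% to 23.2%. Slpi was 6.88 in T30_D0 replicate 1 against 3.04 to 3.53. Epcam was 8255 in T30_D3 replicate 4 against 5290.1 to 5717, and Ptprc 5.27 in T22_D0 replicate 2 against 9.86 to 10.7.

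DSS day 3 against day 0 gave a different change at 30 °C than at 22 °C for 3213 genes by the interaction test in limma (1484 to 4274 with 1 library left out, each that moves the count being named with the comparison). The mean log2 difference was 2.06 over the antigen presentation list and 0.83 over the interferon list. The response at 30 °C was higher for Apol9b (5.10), H2-Ab1 (4.26), H2-Aa (4.24), Cd74 (3.44), Oas3 (3.43), Gzma (2.87), Cd8a (2.63), Irf7 (2.35), Ces1g (1.92), Idh2 (1.33), Nqo1 (1.31) and Mdh2 (0.96) on the log2 scale. It was lower for Naa15 (-3.53), Il7 (-3.48), Abca1 (-3.39), Clca1 (-2.50), Sytl2 (-2.43) and Muc2 (-1.09). It gave a different change with the agonist than with vehicle for 120 genes by the interaction test in limma (57 to 199 with 1 library left out, each that moves the count being named with the comparison). The mean log2 difference was -2.06 over the antigen presentation list and -2.13 over the interferon list. The response with the agonist was higher for Ang4 (3.75), Mptx1 (3.12), Ptger3 (1.72), Nr4a1 (1.70) and Gsta3 (1.38) on the log2 scale. It was lower for Apol9b (-5.08), Clca4b (-4.78), Isg15 (-4.64), Ly6c1 (-4.36), Cd74 (-4.08), Slpi (-3.99), Oasl2 (-3.95), Ly6a (-3.31), Anxa8 (-1.85), Ly6g (-1.60) and Eno1 (-1.15). After the GC correction Mdh2 in the first test and Ptger3 and Gsta3 in the second were no longer called. With GC slope as a term, Gzma (2.64), Idh2 (0.74), Il7 (-2.35), Mdh2 (0.39), Muc2 (-1.35), Naa15 (-1.85) and Sytl2 (-1.57) of the first test were not called. All genes given for the second test kept their call in that fit.

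Other splits of the same libraries into groups of 4 were counted for each comparison. For DSS at 22 °C the real split gave 239 genes and the highest other split 1, with 1 of 35 splits as large. The same share held for DSS at 30 °C with vehicle (7647 against 4626), housing on DSS day 3 (6364 against 3918) and the agonist at day 0 (2201 against 1). It is the smallest share that 35 splits can give, and the 9 comparisons were not adjusted for. It therefore argues against chance without excluding it. The DSS by housing interaction had 2 of 100 splits as large, with another split at 4387 against 3213. The splits of both interactions shuffled labels over all groups compared, day 0 with DSS day 3. The DSS change itself can thus enter their counts, so their shares do not decide on chance. All splits take libraries as exchangeable, while same-numbered libraries of some groups lay close together. The share was above 0.05 for DSS at 30 °C with the agonist (5454 against 5682, 2 of 35), which does not argue against chance. There the larger split exchanges T30_CL_D0 replicate 3 with T30_CL_D3 replicate 1. Nor does the share argue against it for the agonist on DSS day 3 (60 against 2581, 7 of 35) or the DSS by agonist interaction (120 against 7180, 6 of 100). For the agonist on DSS day 3, a split with many times the real count points to a structure of the samples. The high count of the interaction does not, since its splits mixed day 0 with DSS day 3 libraries. The largest split of the agonist comparison on DSS day 3 put T30_D3 replicates 1 and 4 with T30_CL_D3 replicates 1 and 2. In these libraries the deposited values summed to 4.12e+06 to 4.45e+06, against 4.97e+06 to 5.56e+06 in the others. That measure was picked after the data were seen, and a cause was not tested. Housing at day 0 called 0 genes (highest other split 1), so all 35 of 35 splits were bound to call as many and the count tests nothing.

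The changes with DSS at 30 °C with vehicle followed transcript GC content, with a Spearman correlation of 0.580 between log2 fold change and GC content. It was taken across all tested genes with known GC content, called or not. Against GC and length bias as the whole source, 58.6% of the 7647 called genes stayed called with the same sign after the correction. A preparation or RNA quality shared by the DSS day 3 libraries at 30 °C stays open, since 8 of 8 have a GC slope above every day 0 vehicle library, and group and preparation cannot be told apart. A response of the epithelium to DSS at 30 °C stays open too, as untested. With GC slope as a term 565 genes were called, so the number that may be put down to DSS is not settled.

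All 20 measured antigen presentation genes were higher with DSS at 30 °C with vehicle, of which 18 after the GC correction, which argues against that bias. Cd74 rose from 82.4 to 4583. The summed rise of 11 macrophage and B cell markers was 8.04% of that rise, but 1.20% to 51.9% in single libraries, which decides nothing, since Ctss and Cd14 among them were already above Cd74 before DSS. The 9 markers below Cd74 before DSS had a summed rise of 1.83% of the rise of Cd74 (0.203% to 7.44% in single libraries). This set was chosen after the data were seen and leaves out Ctss and Cd14. It therefore does not decide on carried-over macrophages or B cells, which stay open. Against T cells as the whole source, 8 of their markers had a summed rise of 4.02% of the rise of Cd74 (1.47% to 19.8%). A smaller share of T cells was not tested and stays open. Dendritic cells carry CD45, by which cells were to be removed, and were not tested. Ptprc, which encodes CD45, went from 9.11 ± 2.27 to 3.98 ± 2.80 (log2 fold change -1.14 ± 0.66, adjusted p = 0.132) and stood at 0.57 after the GC correction. It passed in neither and does not exclude them. Dendritic cells, macrophages, B cells or a rise within the epithelium may each account for the pattern.

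The agonist changes at day 0 lay close to the DSS changes at 22 °C, with 215 of 239 genes shared. Against GC and length bias, the correlation across genes was 0.646 after the correction and 0.716 before. Preparation of T30_CL_D0 and T22_D3 together stays open: 1 of 8 libraries lay nearest to a library outside both groups, and the labels give no preparation dates. Exchanged labels between both groups stay open as well, since limma called 0 genes between them, with 698 at an unadjusted p under 0.05 where chance gives 593. A shared response to agonist and injury may also account for it, and was not tested.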

How the results depend on the processing

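The GC and length correction, GC slope as a term, deposited scaling and pseudocounts were chosen after the data were seen, and the other settings were planned. The planned DESeq2 alternatives were not run, since the values are not counts. Of 255 gene and comparison pairs named, 3 reversed in any setting, and 134 kept direction and call in all. The 85 list tests called with the preset correlation became 6 with an estimated one. Limma voom and a pseudocount of 5 each called 1 gene for housing at day 0 in place of 0. With only the compared groups in the fit, DSS at 30 °C with the agonist gave 3549 genes, the agonist on DSS day 3 5 and the DSS by agonist interaction 53; the cause was not tested. Median-of-ratios scaling gave 26 genes shared by all 3 DSS responses and 27 by 22 °C and 30 °C with agonist; a stricter filter, which tests fewer genes, gave 24 and 25, and 104 by 22 °C and 30 °C with vehicle. The GC correction gave 1085 genes for the agonist at day 0, 131 for the agonist on DSS day 3, 203 for the DSS by agonist interaction and 2950 shared at 30 °C by vehicle and agonist. With replicate block added these were 1051, 149, 221 and 2994, and 360 for DSS at 22 °C. GC slope as a term gave 565 for DSS at 30 °C with vehicle, 258 with agonist, 1215 for housing on DSS day 3, 183 and 114 for the agonist at day 0 and day 3, and 267 for the interaction with the agonist. For the interaction with housing it gave 148 higher and 95 lower, 2.4e+02 in all. It gave 1 gene shared by all DSS responses, 62 by 22 °C and 30 °C with vehicle, 1 by 22 °C and 30 °C with agonist and 75 at 30 °C. The agonist and housing correlation reversed at day 0 to -0.0258 as the mean of 6 splits of the shared libraries, which lay on both sides of 0 (-0.275 to 0.173). Sharing vehicle libraries alone raises r, and the split removes that share, so a fall follows from the design. On DSS day 3 the correlation reversed to 0.163 after the GC correction, and the cause was not tested. With 1 library left out, the ranges were 76 to 237 for DSS at 22 °C, 6813 to 7899 and 3592 to 6643 for DSS at 30 °C with vehicle and agonist and 4919 to 6835 for housing on DSS day 3. They were 400 to 3400 and 17 to 384 for the agonist at day 0 and day 3, and 1484 to 4274 and 57 to 199 for the interactions with housing and agonist. Ranges of shared genes were 9 to 96 for all 3 responses, 53 to 238 for 22 °C and 30 °C with vehicle, 9 to 101 for 22 °C and 30 °C with agonist and 3178 to 5632 at 30 °C. Those of the agonist and housing correlation were -0.00128 to 0.393 at day 0 and -0.286 to 0.131 on DSS day 3. Housing at day 0 stayed at 0 in all 8 such fits, where the log2 fold changes that did not pass the test ranged over 0 for Epcam (-0.00701 to 0.0441), Lgr5 (-0.0169 to 0.432) and Ptprc (-0.204 to 0.177). With replicate number as a block the counts were 246, 7748 and 5478 for DSS at 22 °C and at 30 °C with vehicle and agonist, 0 and 6383 for housing, 2097 and 73 for the agonist, and 3043 and 124 for the interactions. No comparison had all 4 same-numbered correlations above 0.1, so numbers were not treated as pairs. Between T22_D0 and T30_D0, however, 8 of 8 libraries were nearest to their own number in the other group. A block shared by all 6 groups does not model pairs of only these groups. At these depths, a 1.5-fold change was recovered for 20.9% of simulated genes, and for 8.96% with the GC trends of the real libraries, so most changes of that size would be missed.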

Other observations

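Further gene lists, not described with the comparisons, had called members in both directions at 30 °C, and camera called none of the 3 lists of this paragraph. Among heat shock proteins, which fold and protect other proteins, 5 of 21 rose and 8 fell with DSS and vehicle (5 higher and 8 lower adjusted over the list alone), with Dnajb1 higher (1.26 ± 0.17) and Hspa4l (-2.29 ± 0.34) and Hspa4 (-2.03 ± 0.41) lower (-1.39 and -1.07 after GC correction; camera adjusted p = 0.743, and 0.828 with an estimated correlation). With GC slope as a term Hspa4l (-0.89) and Hspa4 (-0.17) were not called, and Dnajb1 (0.84) was. With the agonist 2 members of this list rose and 7 fell (2 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.558). On DSS day 3, genes of bile acid handling were higher at 30 °C than at 22 °C for 5 of 12 members and lower for 3 (5 higher and 3 lower adjusted over the list alone), with the exporter subunit gene Slc51a (1.82 ± 0.28) and the sulfotransferase gene Sult2b1 (1.58 ± 0.23) higher (camera adjusted p = 0.412). Of the circadian clock list, 4 of 17 members were higher and 4 lower at 30 °C (4 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.998), with Clock at -1.94 ± 0.33 (-0.56 after GC correction) and Dbp at 2.06 ± 0.47.

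In the DSS by housing interaction, 7 of 21 tricarboxylic acid cycle genes had a higher response at 30 °C and 1 a lower one (9 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0336, and 0.295 with an estimated correlation), with Idh2 (1.33 ± 0.29) and Mdh2 (0.96 ± 0.27), which lost its call after GC correction (adjusted p = 0.0525). Ly6g, the only measured member of the neutrophil list, which was too short for a list test, rose with DSS at 22 °C (1.22 ± 0.25) and with the agonist at day 0 (1.70 ± 0.25), and had a lower DSS response with the agonist than with vehicle (-1.60 ± 0.36).

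In 6 of 15 pairs of groups, libraries with the same replicate number were the closest of the 24 possible matchings. After GC correction this held in 2 of them and was lost between T22_D0 and T30_CL_D0, T22_D0 and T30_CL_D3, T22_D3 and T30_D3, and T30_D0 and T30_CL_D3. It held between T22_D0 and T30_D0 and between T22_D3 and T30_CL_D0. Single libraries of these pairs were nearest to their own number in the other group for 8 of 8 and 5 of 8 by differences relative to read sampling, without GC correction. By the distance of log2 values over all tested genes, 6 of the first 8 had that library as the nearest of all libraries (5 after GC correction). The closest pair of libraries from any groups was T22_D3 replicate 1 and T30_CL_D0 replicate 1, whose differences were 1.49 times those of read sampling alone, against at least 2.29 within a group.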
